A study of Homo sapiens with 4 samples.

How the data were processed

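RNA sequencing read counts per gene were analysed for 4 libraries of SAS cells, a line derived from a human tongue squamous cell carcinoma. Per the labels, 2 libraries received a control siRNA (siControl, replicates 1 and 2) and 2 received an siRNA against NAT10 (siNAT10, replicates 1 and 2). Groups and replicate numbers were taken from the sample titles. The genotype label reads as a knockdown of NAT11, another name of NAA40, in siNAT10 replicate 2, so NAA40 was reported beside NAT10.

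Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with the KC Digital mRNA kit and sequenced in paired-end mode. Per the submitters' processing notes, the authors used fastp 0.23.4, STAR 2.5.3a, featureCounts and the GRCh38 build. The annotation release, the strand setting, the use of any molecular identifiers to collapse PCR copies, and the roles of these tools are not given in the sources used here. The deposited values are raw counts per gene in 1 table of 35767 rows. No row was 0 in all 4 libraries. Between 72.0% and 73.5% of the counts from 1 to 50 in a library were even numbers, as counting both mates of a read pair separately would give, so a count is nearer to a mate than to a fragment. Reads in overlapping genes were counted for each gene. In siControl replicate 1, EEF1G had 40892 counts and the read-through gene RP11-864I4.1, which shares its exons, had 41341. Of the tested rows, 50.9% overlapped another row in their exons. Values of genes with an overlapping row, an antisense partner or near-identical copies are therefore uncertain, and such partners are named beside them. In the table, 12 gene names had been turned into dates, and these rows were kept under the deposited name.

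Gene positions are those in the deposited table. Of 24710 names shared with GENCODE release 29 (GRCh38), 23035 had the same gene start and end there. A biotype was assigned to 35306 rows by name, synonym or position, and 17609 of these were protein coding. GC content came from the longest transcript of each gene in the same annotation, and gene length from the deposited table.

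Total counts ranged from 30794757 to 36341785 per library. A floor of 3 counts corresponded to 0.0826 to 0.0974 CPM, that is counts relative to the library total. Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust shrinkage, glmQLFTest) after filtering with filterByExpr by group and scaling with TMM factors. The design held the group only, with 2 residual degrees of freedom per gene before shrinkage. Tests were two-sided, with Benjamini-Hochberg adjustment over 20098 genes and a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, as mean and SD over the 2 libraries of a group, and log2 fold changes are siNAT10 minus siControl with their standard error (SE). Intervals cover the spread between these libraries and counting error, not the effect of PCR copies.

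Before the data were examined, 36 gene lists with 1082 entries were written down, of which 1048 were found in the table. Lists could share genes. The 32 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its p-value on the 2 residual degrees of freedom. Even a clearly shifted list can then miss the threshold after adjustment. Named genes also followed a rule set beforehand. NAT10, NAA40 and DDIT4 were always named. To these were added the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those called, with at least 10 CPM in the higher group and no overlap between groups, and up to 4 called members of each list with the smallest adjusted p. Where no member was called, the 2 with the largest change could be named. Some genes that the rule names are not reported here.

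On simulated counts with the means and library sizes of these libraries, with 50 genes changed at each fold over 20098 genes tested, the test recovered 22% of genes changed 1.25-fold, 42% at 1.5-fold, 68% at 2-fold and 100% at 4-fold. Of all calls in that simulation, 7.14% were false. Only these genes and a shifted list were changed there, against 8120 genes called in the data. Recovery and false calls depend on how many genes change, so these figures need not hold for the data. A list shifted 1.3-fold in the simulation was called by camera with the preset correlation and reached an adjusted p of 0.0528 with an estimated one. Genes were drawn independently there, so the latter value reflects the 2 residual degrees of freedom and not correlated genes.

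Libraries of 1 group were compared before averaging. Their counts differed beyond sampling noise, with a chi-square per degree of freedom of 8.68 for the siControl pair and 5.14 for the siNAT10 pair, so neither pair was 1 library deposited again. Alternatives set beforehand were DESeq2 size factors, library totals without composition factors, upper-quartile factors, no count filter, a filter of 50 counts in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, no robust shrinkage, a test against a fold change of 1.5 (glmTreat), the replicate number as a block, protein-coding genes only, removal of mitochondrially encoded genes, and each library left out in turn. Halved counts and removal of all rows that overlap another were added after seeing the data. No library was left out of the main comparison.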

Results

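Gene expression was profiled in SAS cells, a human tongue squamous cell carcinoma line, in libraries labelled as treated with a control siRNA or with an siRNA against NAT10. NAT10 is the acetyltransferase that places acetylcytidine on ribosomal, transfer and messenger RNA. The title of the series places the comparison in a study of NAT10, acetylcytidine on DDIT4 mRNA and the proliferation of head and neck carcinoma cells. Each group held 2 libraries. Total counts were 36341785 and 36068532 in siControl replicates 1 and 2, and 35896415 and 30794757 in siNAT10 replicates 1 and 2. The labels call them biological replicates without naming separate cultures, so p-values measure only the spread between these libraries, which may be technical.

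The mRNA of NAT10, the target of the siRNA, was not lower in the libraries labelled siNAT10. NAT10 (chromosome 11, 34105602 to 34147670, GRCh38) had 240.4 and 231 CPM in siControl replicates 1 and 2, and 253 and 248 CPM in siNAT10 replicates 1 and 2. Its log2 fold change was 0.09 ± 0.06 (SE, n = 2 per group, edgeR quasi-likelihood adjusted p = 0.293), with a 95% interval from -0.046 to 0.221. These counts therefore do not show the knockdown that the labels name, and every direction given from here on is that of the libraries labelled siNAT10 against those labelled siControl. NAA40 (chromosome 11, 63938959 to 63957328), which the genotype label of siNAT10 replicate 2 names, had 22.1 and 18.8 CPM in the siControl libraries and 18.6 and 18.2 CPM in the libraries labelled siNAT10. Its log2 fold change was -0.15 ± 0.10 (edgeR adjusted p = 0.255), and it passed the threshold when libraries were scaled by their totals alone (-0.26, adjusted p = 0.049, range over 17 alternatives 0.049 to 0.866). THUMPD1, which assists NAT10 in acetylating transfer RNA and overlaps AC004381.8, was at 42.1 CPM in siControl and 35.2 CPM in siNAT10, a log2 fold change of -0.26 ± 0.08 (edgeR adjusted p = 0.0161, not passing without siControl replicate 2, adjusted p = 0.0517, or without siNAT10 replicate 2, adjusted p = 0.188, and passing in the other 14 of 16 alternatives). NAT10 and its partner THUMPD1 made up the list of the acetylcytidine writer and partners, too small for a list test. Of its 2 members only THUMPD1 was called lower, also when adjusted over the list alone.

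DDIT4, which encodes a stress-induced inhibitor of mTORC1, was lower in both libraries labelled siNAT10. DDIT4 (chromosome 10, 72273920 to 72276036) had a mean of 301 CPM (SD 29.7, n = 2) in siControl and 101 CPM (SD 23.1, n = 2) in the libraries labelled siNAT10, which was 2.98-fold lower. The log2 fold change was -1.57 ± 0.16 (edgeR adjusted p = 6.15e-04). Its exons overlap those of RP11-442H21.2. The call was lost when siControl replicate 1 was left out (-1.67, adjusted p = 0.116) and when siControl replicate 2 was left out (-1.47, adjusted p = 0.131), and held in the other 14 of 16 alternatives, with both libraries labelled siNAT10 below both siControl libraries.

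**Figure D1:**
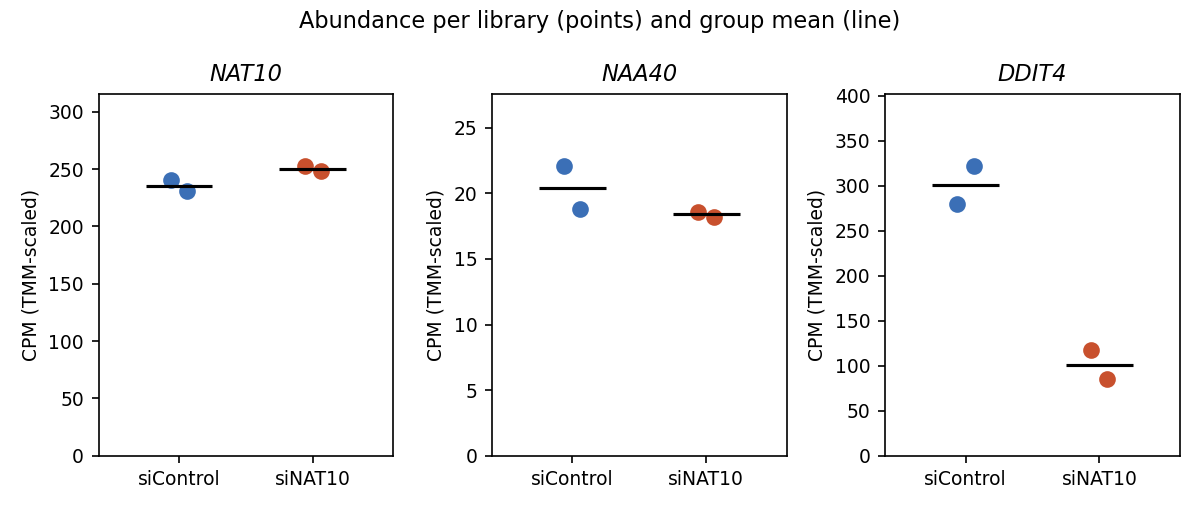
Abundance of NAT10, NAA40 and DDIT4 in CPM on TMM-scaled library sizes, with 1 point per library and a line at the group mean, for siControl and the libraries labelled siNAT10. NAT10 lies between 231 and 253 CPM in all 4 libraries, while DDIT4 lies at 280.3 and 322 CPM in siControl and at 117 and 84.7 CPM in siNAT10.

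The genes with the largest rise included secreted matrix-associated proteins, a growth factor subunit and cancer-testis antigens. ANKRD1, a nuclear and sarcomeric ankyrin repeat protein, rose 11.9-fold from 1.52 CPM (log2 fold change 3.57 ± 0.15, edgeR adjusted p = 1.15e-12). CYR61 (now CCN1), a secreted matricellular protein, rose from 20.6 to 151 CPM (2.88 ± 0.08), and its relative CTGF (now CCN2) rose from 6.65 to 50.4 CPM (2.92 ± 0.10), although CTGF overlaps RP11-69I8.3. INHBA, which encodes the subunit of activin A, rose 3.88-fold to 45.7 CPM. The junction protein gene CGNL1 (overlapping CTD-2515H24.4), the laminin chain gene LAMA1 (overlapping RP11-76K13.3 and RP11-781P6.1) and the phosphatase subunit gene PPP2R2B (overlapping a 5S_rRNA row) rose by log2 fold changes of 2.58, 1.88 and 1.71. The cancer-testis genes MAGEA12 (2.62), CSAG1 (2.24), GAGE1 (2.32) and GAGE2A (2.30) and the pregnancy glycoprotein gene PSG4 (2.82) rose too. Of these, GAGE1 and GAGE2A overlap each other, MAGEA12 overlaps CSAG4, and the GAGE, MAGEA, CSAG and PSG genes have near-identical copies, so reads could not be assigned to single members with certainty.

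The genes with the largest fall included innate immune genes, an NAD synthesis enzyme and collagens. QPRT, an enzyme of NAD synthesis from tryptophan, fell from 57.2 to 5.03 CPM (log2 fold change -3.50 ± 0.10, edgeR adjusted p = 6.29e-15), with AC009133.22 overlapping it. The chemokine gene CCL5 fell from 12.4 to 1.14 CPM (-3.45 ± 0.18), and INHBE, an activin subunit gene, fell from 29.9 to 3.30 CPM (-3.16 ± 0.13). CFB, the complement factor B gene, fell from 194 to 23.1 CPM (-3.07 ± 0.08). The read-through row XXbac-BPG116M5.17 shares exons with CFB and fell alike (-3.08), so both are 1 signal, and C2 overlaps both. The proteoglycan gene SPOCK1 fell by 2.84 on the log2 scale. The collagen genes COL17A1, a hemidesmosome component, and COL6A2 fell, with log2 fold changes of -2.67 and -2.54. The interferon-induced genes OASL, IFI44 and DDX58 (RIG-I, a sensor of viral RNA) fell too, with log2 fold changes of -2.49, -2.40 and -2.39. All of these genes with the largest rise or fall had an edgeR adjusted p of at most 5.49e-09 and kept direction and call under each alternative that tested them.

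**Figure D2:**
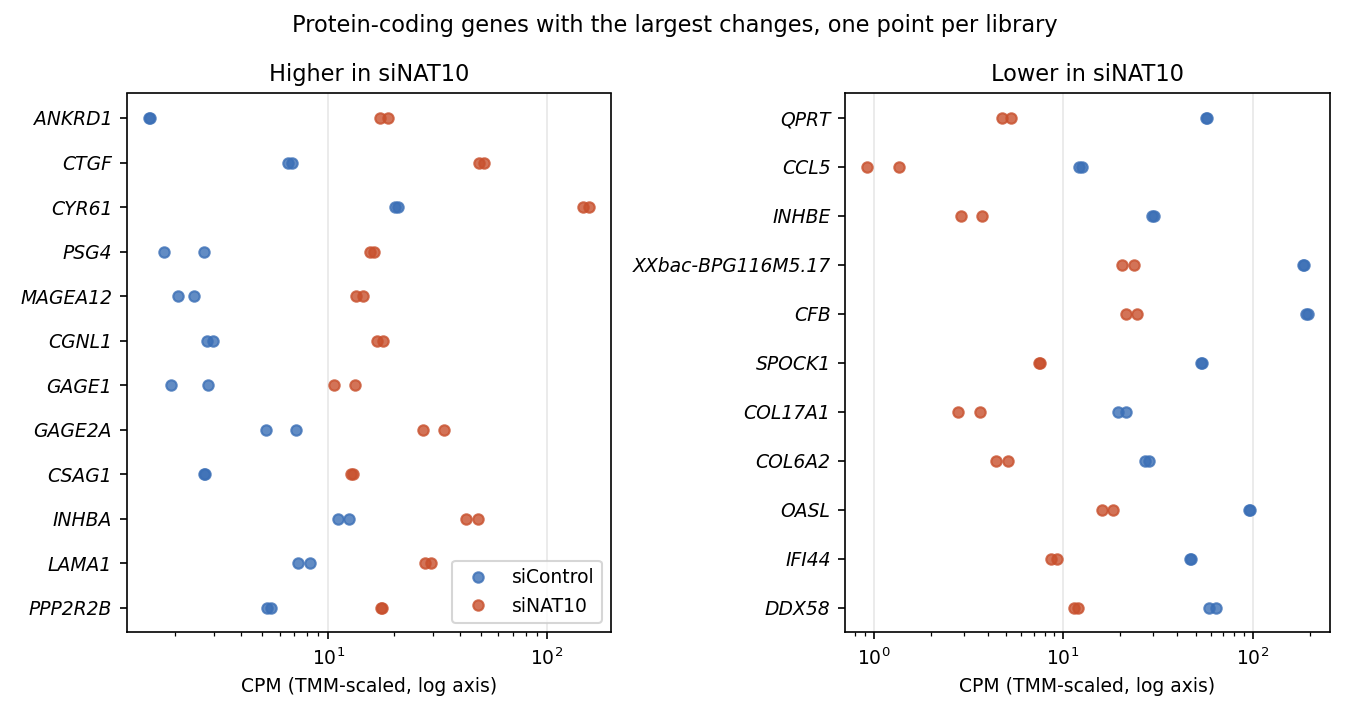
CPM on a log axis, with 1 point per library, of the protein-coding genes reported here with the largest rise (left) and the largest fall (right) in the libraries labelled siNAT10. The libraries of a group lie close together, as for CYR61 at 20.2 and 20.9 CPM in siControl against 146 and 156 CPM in siNAT10.

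Over the whole table, 8120 of 20098 tested genes (40.4%) differed, of which 3951 were higher and 4169 lower in the libraries labelled siNAT10. At least 2-fold changes were called for 551 higher and 1130 lower genes, a total of 1681 that was 1020 with the 50-count filter, 1063 with protein-coding genes only and 969 without overlapping rows, where fewer genes were tested. All calls fell less, to 7556 with the 50-count filter and 6760 with protein-coding genes only. Calls of at least 2-fold thus lay more often in low-count and non-coding rows. With libraries scaled by their totals alone, 2688 genes were higher and 5604 lower, a share of 32.4% higher against 48.7%, and the median gene stood at -0.12 on the log2 scale. A test against a fold change of 1.5 called 478 higher and 940 lower genes, 1078 of them at least 2-fold. The groups' CPM did not overlap for 69.5% of genes, where chance gives 33.3% for 2 libraries against 2. Log2 CPM correlated at 0.992 and 0.991 across genes within the siControl and siNAT10 pairs and at no more than 0.973 between groups.

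Genes induced by type I interferon fell together. Of 39 measured members, 31 fell and 1 rose (32 and 1 adjusted over the list alone), 24 of them fell at least 2-fold, and the median log2 fold change was -1.17 (camera adjusted p = 1.5e-16, but adjusted p = 0.101 with an estimated correlation). Besides OASL and DDX58, IFIT3, a member of an antiviral RNA-binding complex, fell from 194 to 49.9 CPM (log2 fold change -1.96 ± 0.07), and the ubiquitin-like modifier gene ISG15 fell from 230.1 to 57.7 CPM (-2.00 ± 0.07, overlapping RP11-54O7.10). Among 21 measured NF-kB and inflammatory genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 3.82e-05, and adjusted p = 0.179 with an estimated correlation). These included the prostaglandin synthase gene PTGS2 (-1.50 ± 0.16), the NF-kB inhibitor gene NFKBIA (-0.95 ± 0.10) and TNFAIP2 (-0.69 ± 0.06).

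Targets of ATF4, the transcription factor of the integrated stress response, fell as a group. Their list also holds ATF4 itself. Of 36 members, 32 fell and 2 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.84 (camera adjusted p = 1.5e-16, and adjusted p = 0.101 with an estimated correlation). The stress regulator NUPR1 fell from 204 to 58.5 CPM (log2 fold change -1.80 ± 0.07), asparagine synthetase ASNS from 74.4 to 28.2 CPM (-1.40 ± 0.08) and PHGDH, the first enzyme of serine synthesis, from 441 to 219 CPM (-1.01 ± 0.06). In the unfolded protein response of the endoplasmic reticulum, 16 of 30 members fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 2.83e-04, and adjusted p = 0.329 with an estimated correlation), among them the transcription factor gene XBP1 (-0.94 ± 0.08) and HERPUD1 (-0.75 ± 0.08). Of 27 p53 targets, 12 fell and 5 rose (13 and 5 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 9.72e-03, and adjusted p = 0.365 with an estimated correlation). The cell cycle inhibitor gene CDKN1A fell from 24.3 to 9.56 CPM (-1.35 ± 0.10), and SESN2, which is also an ATF4 target, fell by 1.52 on the log2 scale. The p53 median was -0.39 without siNAT10 replicate 2 and -0.38 without overlapping rows.

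Apoptosis regulators, hypoxia targets and NRF2 targets also leaned down, by smaller medians. Of 33 apoptosis regulators, 16 fell and 4 rose (17 and 5 adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 9.54e-03, and adjusted p = 0.276 with an estimated correlation). The pro-apoptotic genes PMAIP1 and BBC3 (overlapping MIR3190) fell, with log2 fold changes of -1.79 and -1.19, while BIRC5, a survival and mitotic gene, rose by 0.76 ± 0.07. BBC3 is also in the p53 list and BIRC5 in the mitosis list. Of 32 hypoxia targets, 13 fell and 4 rose (13 and 5 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0219, and adjusted p = 0.276 with an estimated correlation), including the glycoprotein hormone gene STC2 (-1.09 ± 0.07). STC2 is also in the ATF4 list. Of 26 NRF2 targets, 12 fell and 6 rose (13 and 8 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0398, and adjusted p = 0.422 with an estimated correlation). The aldo-keto reductase genes AKR1C2 (-1.77) and AKR1C3 (-1.23), which are close paralogs (RP11-499O7.4 overlaps AKR1C3), and the cystine transporter gene SLC7A11 (-1.01, overlapping SLC7A11-AS1) fell. Without overlapping rows, the list calls were lost for apoptosis (camera adjusted p = 0.176, median -0.077), hypoxia (0.656, median -0.11) and NRF2 (0.954, with a median of 0.15), of which the first and second held in the other 15 of 16 alternatives. The NRF2 call was also lost with the 50-count filter (0.0689), with protein-coding genes only (0.069) and with halved counts (0.0525), with medians from -0.23 to -0.19, and held in 12 of 16. Without siControl replicate 2 the apoptosis and hypoxia medians were -0.14 and -0.11.

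Genes of mitosis rose, while genes of S phase went both ways. Of 49 genes of mitosis and G2/M, 42 rose and 1 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.52 (camera adjusted p = 3.9e-17, and adjusted p = 0.101 with an estimated correlation). The checkpoint kinase gene BUB1 rose from 93.5 to 182 CPM (log2 fold change 0.96 ± 0.07), the cytokinesis gene ANLN from 548 to 1144 CPM (1.06 ± 0.06, overlapping KIAA0895), and the mitotic kinesin gene KIF23 from 98.1 to 194 CPM (0.99 ± 0.07, overlapping RP11-253M7.1). Of 48 genes of DNA replication and S phase, 11 rose and 9 fell, also when adjusted over the list alone, with a median of -0.0013, a mean of 0.01 and an upward, uncalled test (camera adjusted p = 0.722). The ribonucleotide reductase gene RRM1 rose by 0.52 ± 0.06 (overlapping RRM1-AS1), and the transcription factor gene E2F1 fell by 0.62 on the log2 scale. Of 29 measured entries for MYC and its targets, 23 rose and 2 fell, also when adjusted over the list alone, with a median of 0.42 (camera adjusted p = 1.1e-10, and adjusted p = 0.102 with an estimated correlation). The transferrin receptor gene TFRC rose from 43.0 to 88.3 CPM (1.04 ± 0.07). Other leading members are shared with lists given below, the nucleolin gene NCL with the nucleolus and HSPE1 with the heat shock response. HSPE1 overlaps HSPD1 and HSPE1-MOB4.

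Genes of ribosome assembly and of the cytosolic heat shock response rose. In the list of large-subunit biogenesis and the nucleolus, 32 of 39 members rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 0.47 (camera adjusted p = 3.58e-13, and adjusted p = 0.101 with an estimated correlation). The nucleolar proteins nucleolin (NCL, from 2909 to 5996 CPM, log2 fold change 1.04 ± 0.06) and nucleophosmin (NPM1, from 2134 to 4418 CPM, 1.05 ± 0.06) led it. Of 46 members of the small-subunit processome, 25 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 1.3e-07, and adjusted p = 0.163 with an estimated correlation), among them RRP9 (1.04 ± 0.09), MPHOSPH10 (0.85 ± 0.06) and DDX10 (0.83 ± 0.06). Of 79 cytosolic ribosomal protein genes, 55 rose and 2 fell (57 and 2 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 2.28e-12, and adjusted p = 0.422 with an estimated correlation). RPLP1 and RPS24 rose by 0.86 ± 0.07 and 0.80 ± 0.08, although ribosomal protein genes share reads with many processed pseudogenes. Genes matched to this list on GC content, length and expression had a median of 0.12 (95% of draws from 0.0096 to 0.21). All 20 heat shock genes rose, also when adjusted over the list alone, with a median of 0.64 (camera adjusted p = 2.95e-16, and adjusted p = 0.102 with an estimated correlation). The chaperone genes HSPA8 (overlapping SNORD14C and SNORD14D), HSPA1A (near-identical to HSPA1B) and HSP90AA1 (overlapping WDR20) rose 2.87-fold, 2.25-fold and 1.96-fold.

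In energy metabolism, respiratory genes of both genomes and glycolytic genes rose. Of 72 nuclear genes of oxidative phosphorylation, 43 rose and 3 fell (44 and 3 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 7.86e-09, and adjusted p = 0.329 with an estimated correlation). The complex I subunit genes NDUFS5 and NDUFA5 rose by 0.62 ± 0.06 and 0.65 ± 0.07. Of 13 mitochondrially encoded mRNAs, 11 rose and none fell (12 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.85e-11, and adjusted p = 0.329 with an estimated correlation), and MT-CO2 rose from 939 to 1992 CPM (1.09 ± 0.08). All mitochondrially encoded rows took 4.79% and 4.74% of counts in siControl and 5.42% and 6.0% in the libraries labelled siNAT10, while the mitochondrial ribosomal RNAs took 1.80% and 1.94% against 1.6% and 1.63%. Of 19 glycolytic genes, 11 rose and 2 fell, also when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.04e-03, and adjusted p = 0.329 with an estimated correlation). PKM and PGK1 rose by 0.57 ± 0.07 each, and the neuronal enolase gene ENO2 fell by 0.72 on the log2 scale. Of 25 genes of cholesterol synthesis and SREBP2 targets, 11 rose and 5 fell (11 and 6 adjusted over the list alone) without a list call (camera adjusted p = 0.0885), and with a list call in 2 of 16 alternatives, without a count filter (0.0492) and without siControl replicate 2 (0.0274). Squalene epoxidase SQLE was at 0.53 ± 0.08. Of 17 genes of fatty acid synthesis, 2 rose and 6 fell (3 and 6 adjusted over the list alone) without a list call (camera adjusted p = 0.318), and the carbohydrate-responsive transcription factor gene MLXIPL fell by 1.35 on the log2 scale.

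**Figure D3:**
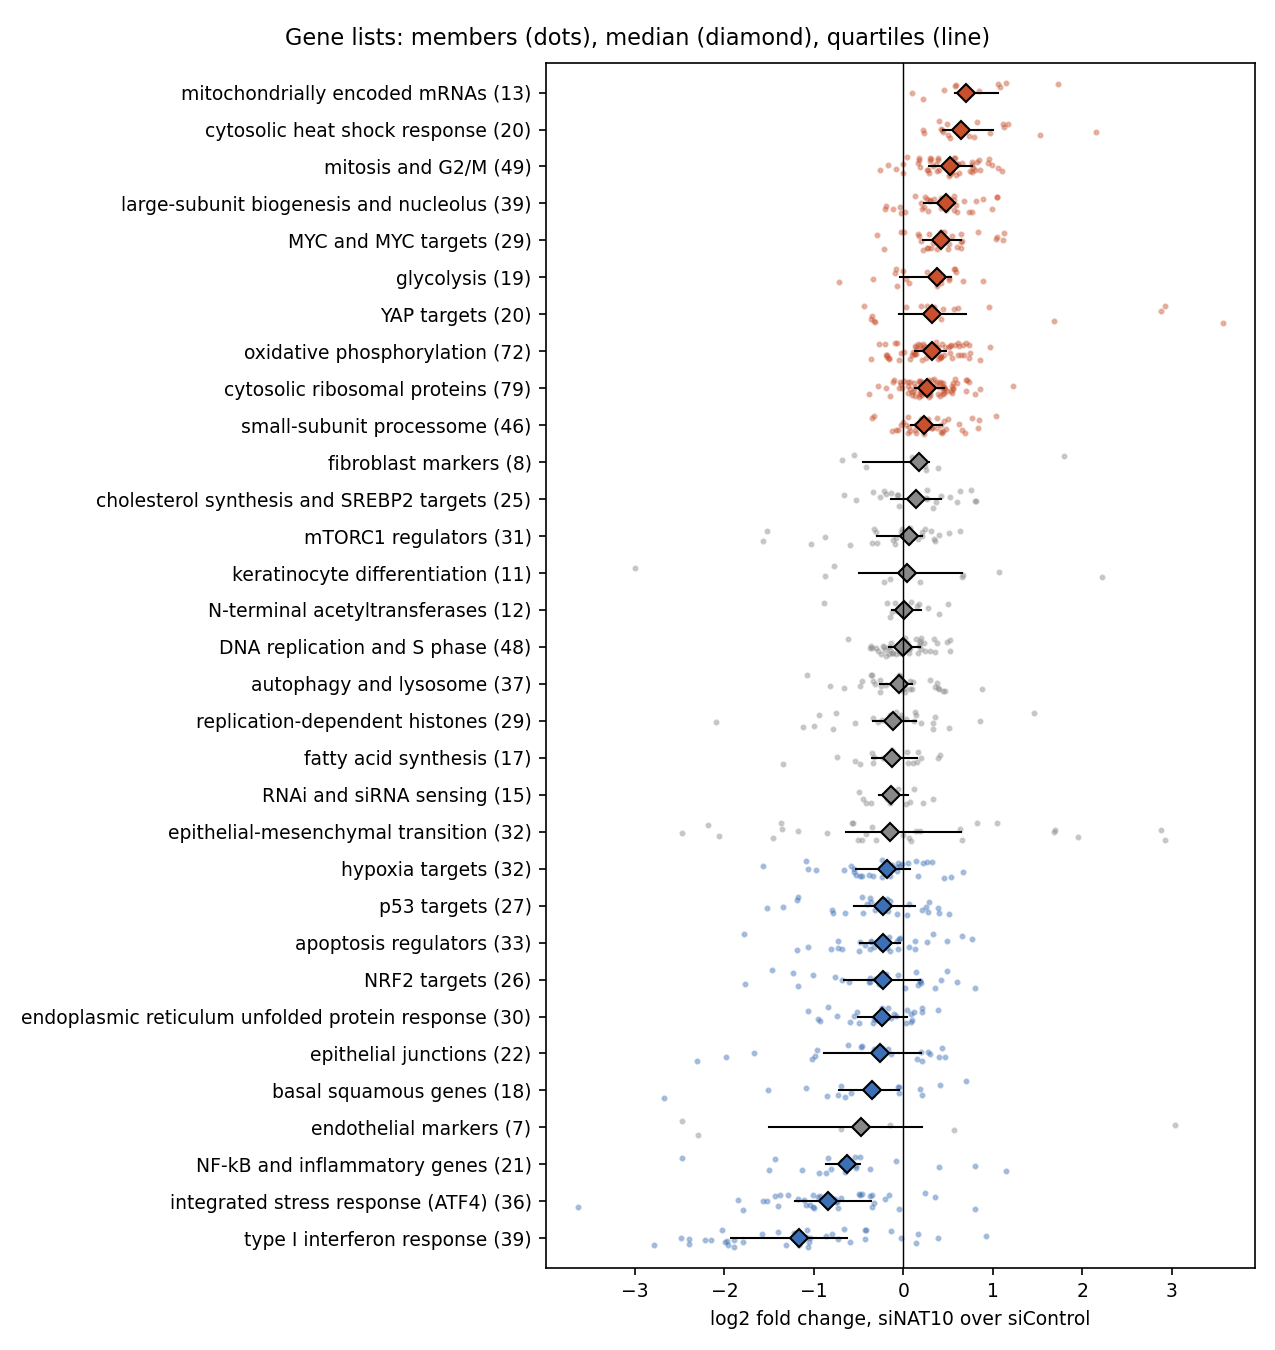
Log2 fold change of the libraries labelled siNAT10 over siControl for the members of the 32 tested gene lists, with members as dots, the median as a diamond, the quartiles as a line and the number of tested members in parentheses. Lists called by camera with the preset correlation are red where the median is positive and blue where it is negative, and the type I interferon list at -1.17 and the mitochondrially encoded mRNAs at 0.70 lie at the ends.

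Targets of the transcriptional coactivator YAP rose on balance, and the lists of basal squamous genes and epithelial junctions were called lower, with at most 0.5 of their members called lower by edgeR. Of 20 YAP targets, 12 rose and 5 fell, also when adjusted over the list alone, with a median log2 fold change of 0.32 (camera adjusted p = 4.27e-04, and adjusted p = 0.179 with an estimated correlation), led by ANKRD1, CTGF and CYR61. The call was lost without overlapping rows (camera adjusted p = 0.132, with a median of 0.30) and held in the other 15 of 16 alternatives. Of 18 basal squamous genes, 9 fell and 1 rose, also when adjusted over the list alone, with a median of -0.35 (camera adjusted p = 3.36e-04, and adjusted p = 0.179 with an estimated correlation). Besides COL17A1, the hemidesmosome integrin gene ITGB4 fell from 108 to 65.1 CPM (-0.73 ± 0.07), and the keratin genes KRT16 (-1.51 ± 0.10) and KRT17 (-0.58 ± 0.07), which have close paralogs and pseudogenes, fell. Of 22 genes of epithelial junctions, 9 fell and 5 rose (10 and 6 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.049, and adjusted p = 0.329 with an estimated correlation). The tight junction gene TJP3 (-1.98 ± 0.14) and the desmosomal cadherin genes DSC3 (-1.67 ± 0.16) and DSC2 (-0.97 ± 0.10) fell. That list's call was lost with the 50-count filter (camera adjusted p = 0.0908), with protein-coding genes only (0.0882), without mitochondrial genes (0.051), with halved counts (0.0642) and without overlapping rows (0.123), with medians from -0.27 to -0.24, and held in 11 of 16 alternatives. Of 32 genes of epithelial-mesenchymal transition, 9 rose and 12 fell, also when adjusted over the list alone, with a median of -0.15, no list call (camera downward, adjusted p = 0.722) and an upward direction by fry. The laminin chain gene LAMB3 fell from 295 to 114 CPM. Of 11 measured genes of keratinocyte differentiation, 3 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of 0.04, a mean of -0.02 and no list call (camera adjusted p = 0.967). KRT10 rose by 0.66 ± 0.12 (overlapping TMEM99), and ECM1 fell by 0.88 on the log2 scale.

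The other lists were not called by camera with the preset correlation. Of 31 regulators of mTORC1, 5 rose and 9 fell, with a median log2 fold change of 0.07, a mean of -0.11 and a downward, uncalled test (camera adjusted p = 0.595). Besides DDIT4 and SESN2, the translation repressor gene EIF4EBP1 fell from 165 to 90.1 CPM (-0.87 ± 0.08), while RHEB, the GTPase that activates mTORC1, rose from 44.2 to 63.0 CPM (0.51 ± 0.08). Of 12 N-terminal acetyltransferase genes, 3 rose and 1 fell (camera adjusted p = 0.599), the latter being NAA30 (-0.89 ± 0.20), whose call was lost without siNAT10 replicate 2 (adjusted p = 0.0797) and held in the other 16 of 17 alternatives, at -0.49 without siControl replicate 2. Among the genes that rose, NAA20 and NAA16 lost their calls with library totals (edgeR adjusted p = 0.124 and 0.0755). NAA20 also lost its call without siNAT10 replicate 1 (log2 fold change 0.25), and NAA16 without siControl replicate 2. Both calls held in the other 15 of 17 alternatives. NAA16 stood at 0.65 without siControl replicate 1 and at 0.18 without siControl replicate 2. NAA15, which overlaps RP11-83A24.2, passed in 16 of 16 alternatives. Of 37 genes of autophagy and the lysosome, 7 rose and 13 fell (camera adjusted p = 0.474), with the transcription factor gene MITF at 0.88 ± 0.08 and the protease gene CTSB at -0.82 ± 0.08. Of 15 genes of RNA interference and siRNA sensing, 1 rose and 4 fell (camera adjusted p = 0.266), with DROSHA at 0.33 ± 0.06 (0.22 with library totals) and TNRC6A at -0.45 ± 0.07. For these 4 lists the counts were the same adjusted over the list alone. Of 29 measured replication-dependent histone genes, 2 rose and 5 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.633). With an estimated correlation, camera called 0 of the 32 lists, and 7 had an unadjusted p under 0.05. That run rests on 2 residual degrees of freedom, so its lack of calls alone decides little for or against lists whose estimated correlation was low. The estimated correlation was below the preset 0.01 for mitosis (-0.0019), ATF4 targets (-0.017) and interferon genes (-0.0013). It was 0.48 for ribosomal proteins, 0.72 for mitochondrially encoded mRNAs and 0.19 for oxidative phosphorylation, well above the preset. On the same 2 degrees of freedom, their unadjusted camera p with an estimated correlation was 0.258, 0.142 and 0.175. For mitosis, ATF4 targets and interferon genes it was 0.00858, 0.0099 and 0.00979. The preset p-values of the lists with high estimates may therefore be too small. Fry called 21, which left out the ribosomal proteins (fry adjusted p = 0.0672) and took in the N-terminal acetyltransferases (upward, 0.0259) and fatty acid synthesis (downward, 0.0285). With libraries scaled by their totals alone, medians moved to 0.15 for ribosomal proteins, 0.20 for oxidative phosphorylation, 0.12 for the small-subunit processome, 0.21 for YAP targets and -0.29 for hypoxia targets, all still called. The basal squamous median was -0.58 with halved counts and -0.66 without overlapping rows.

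Markers of other cell types stayed low or went both ways. Of 8 fibroblast markers, 2 rose and 1 fell, with a median log2 fold change of 0.17, a mean of 0.14 and a downward, uncalled test (camera adjusted p = 0.978), and COL1A1, the most abundant, fell by 0.42 on the log2 scale. Of 7 endothelial markers, 1 rose and 4 fell (camera adjusted p = 0.26), with EGFL7, which carcinoma cells can also express, at -0.70 ± 0.09 and PECAM1 at no more than 46 counts in any library. The 11 leukocyte markers in the table summed to 55.7 and 58.1 CPM in siControl and 55.4 and 54.6 CPM in the libraries labelled siNAT10, with CD68, a lysosomal gene that overlaps RP11-186B7.4 and AC113189.5, at a mean of 49.0 CPM. Of their 4 tested members, 1 fell. Of 2 tested erythroid markers, 1 fell (HBG2, -0.25 ± 0.09, near-identical to HBG1 and overlapping it, HBE1 and 4 other rows), a call lost with upper-quartile factors (adjusted p = 0.0703), with the DESeq2 Wald test (0.119), without siControl replicate 2 (0.113), without siNAT10 replicate 1 (0.23) and without siNAT10 replicate 2 (0.0701), and held in 11 of 16 alternatives. None of 4 tested markers of hepatic, prostate, melanocyte or neural lines was called by edgeR, including SYP at 0.50 ± 0.30 (adjusted p = 0.201, overlapping SYP-AS1). Counts for these lists were the same adjusted over the list alone.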

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

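Halved counts and the removal of overlapping rows were chosen after seeing the data, and the other settings before. No gene called in the main comparison was called in the opposite direction under any setting. Besides NAT10 and DDIT4, 153 genes were examined singly, most of them called in the main comparison. Of these, 141 genes, and of the 32 lists 19, kept direction and side of the threshold in every setting that tested them. Leaving out 1 library at a time, with the lone library assumed to vary like the pair, gave 6128 to 7795 changed genes, 2895 to 3818 higher, 3233 to 3977 lower and 1483 to 1695 changed at least 2-fold, 20 to 21 lists, NAT10 at 0.06 to 0.12 and DDIT4 at -1.82 to -1.36. DDIT4 passed without either siNAT10 library and not without siControl replicate 1 (-1.67) or 2 (-1.47). With 1 siControl library left out, only the siNAT10 pair (117 and 84.7 CPM) could give spread, and the SE was 0.30. It was 0.11 with 1 siNAT10 library left out, where the siControl pair lay at 280.3 and 322 CPM. Other causes were not tested. The fit with a replicate block called 8254 genes against 8120. Same-numbered libraries did not deviate together (correlation -0.0189 across genes), which shows no large shared effect. Whether they were prepared together is not settled by the labels. The test against a fold of 1.5 called 1418 genes (478 higher, 940 lower, 1078 at least 2-fold), as its stricter null hypothesis requires. Calls of at least 2-fold numbered 1020 with the 50-count filter and 1063 with protein-coding genes only, against 1681. Fewer genes were tested there (15430 and 13901), but all calls fell less, from 8120 to 7556 and 6760. Calls of at least 2-fold thus lay more often in low-count and non-coding rows than calls in general. Without overlapping rows, 9865 genes were tested and 3934 called (1894 higher, 2040 lower, 969 at least 2-fold). With an estimated correlation 0 lists were called by camera, 7 at an unadjusted p under 0.05, and fry called 21, without the ribosomal proteins and with N-terminal acetyltransferases and fatty acid synthesis. That camera run rests on 2 residual degrees of freedom, so its lack of calls decides little where the estimated correlation was low. For ribosomal proteins (0.48) and mitochondrially encoded mRNAs (0.72) it was high, so their preset p-values may be too small. Scaling by library totals turned NAT10 to -0.024, along with the median gene, which moved from -0.0079 to -0.12. The DESeq2 Wald test called 6256 genes.

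Uncalled medians changed sign for the S phase list (0.0052 with DESeq2 size factors, 0.035 with upper-quartile factors, 0.0054 with the Wald test, 0.0074 with protein-coding genes, 0.0018 without mitochondrial genes, 0.0018 without overlapping rows, and -0.030 to 0.026 with 1 library left out), the acetyltransferases (-0.10 with library totals, -0.074 without a filter), keratinocyte differentiation (-0.073 with library totals, -0.057 with halved counts, -0.054 to 0.172 with 1 library left out), mTORC1 regulators (-0.044 with library totals, -0.0024 to 0.0897 with 1 left out), fibroblast markers (-0.236 to 0.327 with 1 left out), histones (-0.154 to 0.00098 with 1 left out) and fatty acid synthesis (0.039 without overlapping rows). The uncalled log2 fold change of the gene ATF4 itself, not of its target list, also changed sign (-0.115 to 0.021 with 1 library left out). The NRF2 median turned to 0.15 without overlapping rows. The cause was not tested for these. Depth limits the markers near the floor, and at 2 libraries per group small changes can be missed.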

Other observations

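The tests on exchanged libraries, on NAA40, on the 7 leukocyte genes, on siRNA sensing, on scaling and on mTORC1, the gene families and the single genes in the next paragraph were chosen after the results were seen, and the tests against matched genes and on the summed leukocyte markers before. Setting list medians against the range of matched draws was added afterwards.

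Some genes of class I antigen presentation, picked after their values were seen and not tested as a list, fell in the libraries labelled siNAT10. HLA-B fell from 842 to 341 CPM (log2 fold change -1.30 ± 0.07, edgeR adjusted p = 2.61e-11) and HLA-C from 1092 to 420 CPM (-1.38 ± 0.07), with reads that these paralogs can share and XXbac-BPG248L24.12 overlapping HLA-B. The peptide transporter gene TAP1 fell by 0.99 and the immunoproteasome gene PSMB9 by 1.26 on the log2 scale (PSMB8-AS1 overlaps both), while B2M, the light chain of class I molecules, was at -0.14 ± 0.06 (adjusted p = 0.0885, range over alternatives 0.00367 with library totals to 0.454). MYC itself fell by 0.29 (adjusted p = 1.76e-03) although its target list rose.

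Among 218 gene families defined by a shared symbol stem, camera with the preset correlation called 18 up and 4 down. The chaperonin CCT genes (7 of 8 higher, none lower, median log2 fold change 0.48), the TOMM genes of mitochondrial protein import (7 of 9 higher, none lower, 0.51), the translation initiation factors EIF (33 of 54 higher, 6 lower, 0.29) and the mitochondrial ribosomal proteins MRPL (25 of 49 higher, 2 lower, 0.31) were up. The integrin alpha chains ITGA (6 of 9 lower, 1 higher, -0.85) and the collagens COL (15 of 33 lower, 5 higher, -0.55) were down, with ITGA5 (overlapping RP11-753H16.5) at -0.85 ± 0.07 and COL5A1 at -0.56 ± 0.07. Each of these 6 medians kept its sign under all 3 other scalings, but with library totals EIF had 25 higher and 11 lower genes (median 0.18) and MRPL 18 and 5 (0.20). With an estimated correlation camera called 0 families, 0 at an unadjusted p under 0.05, and adjusted p was 0.869 for all 6. That run too rests on 2 residual degrees of freedom, so it decides little for or against the families. Set against genes matched on GC content, length and expression, some called lists kept less of their median than those weighed here, with a share of 0.55 for ribosomal proteins, 0.687 for mitochondrially encoded mRNAs, 0.712 for the small-subunit processome and 0.753 for oxidative phosphorylation.

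NAT10 mRNA was not lower in the libraries labelled siNAT10, although the groups differed in 8120 genes. The other splits of the 4 libraries into pairs called 0 genes each by edgeR and by DESeq2, with 38 and 39 at an unadjusted p under 0.05. Each pair there held a library of either group, so the difference between groups counted as spread and calls were hardly possible. These splits therefore do not bear on the grouping. Each library correlated best with its own group mate, by a margin of at least 0.0175. That goes against an exchange of 1 library between the groups only if the treatment set the main difference between libraries. NAT10 lay between 231 and 253 CPM in all 4 libraries, so no exchange would uncover a large fall of its mRNA. In siNAT10 replicate 2, NAA40 stood at 0.89 of the siControl mean. That goes against an siRNA acting on NAA40 there only if such an siRNA lowered the mRNA until harvest. An exchange of both groups' labels cannot be told apart, since the upper bound of the NAT10 log2 fold change, 0.221, goes against it only if the siRNA lowered the mRNA. Also open and untested are an siRNA that acts on NAT10 protein without lowering its mRNA, recovery of the mRNA before harvest, off-target effects, and libraries from another treatment.

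Type I interferon genes were lower in the libraries labelled siNAT10. Genes matched on GC content, length and expression had a median near 0 (-0.0081, 95% of draws from -0.16 to 0.17) and left 0.993 of the list's median, so these properties do not account for it. Leukocyte RNA in the siControl libraries was tested with the summed markers, whose difference of 1.89 CPM fell between the limits set beforehand (1 and 10), and then with 7 genes, PTPRC, which most leukocytes share, and TYROBP, FCER1G, ITGAM, HLA-DRA, MS4A1 and CD79A of some lineages only, which each reached at most 4 counts in a library and a mean sum of 0.359 CPM in siControl, far below what leukocytes would bring. Sensing of the control siRNA, raising these genes in siControl, cannot be told apart from a lower interferon response in siNAT10 (31 genes lower), since no untransfected library was analysed here. Both remain hypotheses.

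Mitotic and nucleolar genes were higher and ATF4 targets lower in the libraries labelled siNAT10. The choice among the scalings used does not account for this, since the 3 lists kept at least 0.767 of their medians under each. These scalings move all genes nearly alike, with the median gene between -0.12 and 0.029. An error common to all of them was therefore not tested. Matched genes left at least 0.791 of each median, with all 3 medians outside the range of matched draws. For mitosis this was 0.52 against -0.019 to 0.22, which is closer for that list than the share alone shows. Whether mTORC1 activity changed after the fall of its inhibitor DDIT4 cannot be told apart here. The median of -0.759 over the 35 members of the ATF4 list without DDIT4, ATF4 itself included, only restates the pattern. A candidate explanation is that DDIT4 fell as 1 of many ATF4 targets, 3 of which fell more, while ATF4 mRNA was at -0.05 ± 0.07 (edgeR adjusted p = 0.6). ATF4 protein and acetylcytidine were not measured, and faster growth, a weaker stress response or an effect of the siRNA itself stay open as untested.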
